A study of Mus musculus with 7 samples.

How the data were processed

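RNA was measured by sequencing of poly(A)-selected, dUTP strand-specific libraries, per the labels' protocols, in 7 samples of mouse subventricular zone neural stem cells, 4 nucleofected with shRNA against KAP1 and 3 controls. Samples were grouped by the library names in the labels. The control libraries are named 1, 2 and 4, whereas the control titles are numbered 1, 2 and 3, and the labels do not say whether a further control library was made or entered the authors' fit. The submitters' processing notes name Trim Galore 0.4.4, kallisto, DESeq2 and the genome build GRCm38, and the versions of kallisto and DESeq2, the transcript annotation and the model formula are not given in the sources used here.

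The data are the authors' deposited table of 1 comparison, with 1 line per gene and no column per sample. Per the file headers it holds the mean of normalized counts (a signal averaged over samples, deposited by the authors), the log2 fold change and its standard error on the log2 scale, a signed linear fold change, the Wald statistic (a score of the authors' test) and the p-value with its adjusted p-value, as DESeq2 writes them. Checks on the file showed that the signed fold repeats the log2 column and that the Wald statistic is the ratio of the log2 fold change to its error. The table names neither numerator nor denominator, and negative values were read as lower in shKAP1 because Trim28 is negative. Which libraries entered the authors' fit, and whether it had a batch or pairing term, is not stated. The lowest and highest mean normalized counts listed are 5.70 and 512695. Library totals are unknown, so no count interval or detection limit was computed.

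The largest adjusted p listed is 0.0499, so the table holds genes under 0.05 only. Adjusted p times rank divided by p gave 12905, within 0.01, in 85.2% of lines, and the other lines differ through the running minimum of the Benjamini-Hochberg method. This is the number of genes that received an adjusted p, and 9516 of them are not listed. On simulated p-values the same step returned the 12905 tests that were simulated, which follows from the method and checks only the code. Every gene count therefore rests on the authors' test, and nothing was refitted. The fit to counts per sample that was planned was replaced by the fallback fixed in advance for a table of comparisons, which counts listed genes per direction and has no test of gene lists. A count adjusted over a list alone could not be had, since p-values of genes not listed are unknown.

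Gene symbols, biotypes, GRCm38 coordinates and transcript sequences came from GENCODE M21. Of 3389 identifiers, 3278 matched with their version and 3388 without it, and 3378 are annotated as protein-coding. GC content is the median over the annotated transcripts of a gene. Intervals of 95% were computed from the log2 fold change and its standard error under a normal approximation.

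Before the data were examined, 24 gene lists were fixed, covering KAP1 partners, imprinted and germline genes, the Zfp family, interferon response, neural stem cell, neuronal and glial genes, other cell types, cell cycle, p53 targets, signalling, metabolism and stress. Named genes were fixed by rule as a short set that included Trim28, Pax6, Sox2, Dlx2, Dcx, Gfap and Olig2, the 12 genes of smallest adjusted p per direction among those changed at least 2-fold, leaving out unnamed gene models, and up to 4 members per list by adjusted p. Further members named beside them, such as Cdkn1a, Mdm2, Nes, Setdb1, Txnrd1, Zfp57, Peg10 and Cdkn1c, were chosen after their values were seen. List symbols were matched to M21 symbols, or to these through RefSeq synonyms.

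The direction of a list was tested with Fisher's exact test (two-sided) of higher against lower genes among its listed members and all other listed genes, for the 16 lists with at least 5 listed members, with Benjamini-Hochberg adjustment. This test was chosen after the data were seen. It is conditional on a gene being listed and treats genes as independent, which co-regulated genes are not. A second test drew listed genes 10000 times with the same spread over 10 strata of GC content, and 2e-04 was set as its smallest two-sided p. In 200 simulations on the 3389 listed genes, a planted share of 85% higher members in 5 lists of 10 to 13 listed members was recovered in 51.8% of cases, and 0.9% of lists with no planted shift were called. Beyond the 24 lists, 34 gene families defined by symbol prefix were scanned for a common direction after the data were seen. Of these, 28 had at least 5 listed members and were tested in the same way, with adjustment over the 28. The families described in the closing part were picked for their direction or as a contrast, and the prefixes of several, such as the protocadherin, splicing and actin families, were narrowed after their members had been seen, so their p-values understate the search. Alternatives were a stricter adjusted p of 0.01, a 2-fold minimum, a Bonferroni limit, a minimum mean normalized count of 100 and intervals beyond 1.2-fold. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.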

Results

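Neural stem cells were grown from the subventricular zone of the mouse brain, a region where new neurons continue to be made after birth, in medium with EGF and FGF-2. Short hairpin RNA against KAP1 was brought in by nucleofection, and poly(A)-selected, strand-specific RNA libraries were sequenced from 4 shKAP1 samples and 3 control samples. KAP1 is the protein of the gene Trim28, a corepressor that KRAB zinc finger proteins recruit to DNA, and the series asks what its loss does in these cells. The values examined are those of the authors' deposited table, which gives for each gene a mean normalized count, a log2 fold change with its standard error (SE) and a DESeq2 adjusted p. It holds no value per sample, so the depth and the spread of single libraries are unknown, and the SE stands in for the replicate error throughout. Nothing in the labels says whether the samples came from separate cultures or animals, so the p-values measure only the spread between these samples. Negative fold changes were read as lower in shKAP1, because the table does not name its numerator and Trim28 is negative in it.

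Trim28 was lower in shKAP1 by the reading of signs given above, so its direction is not an independent result, unlike its rank and size. Trim28 stands first by adjusted p in the authors' deposited table, with a log2 fold change of -1.17 (SE 0.05, adjusted p = 1.78e-101, DESeq2) at a mean normalized count of 13703. This is a 2.25-fold fall, with a 95% interval of 2.09 to 2.42, and leaves 44.5% of the control level (95% interval 41.4 to 47.9). Trim28 (ENSMUSG00000005566.14) lies on chromosome 7 at 12999114 to 13031035, plus strand, in GRCm38.

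The comparison of shKAP1 with control asks which transcripts differ when Trim28 is reduced. Every listed gene of the DNA replication and mitosis lists was lower, and listed p53 target and apoptosis genes were mostly higher. The changes were small. Of the neural stem cell genes that were listed most were higher, but 27 of 40 were not listed and the call did not hold on the fewer members left under 2 of the stricter limits or without members shared with other lists. The authors' deposited table lists 3389 genes with an adjusted p under 0.05, of which 1621 were higher and 1768 lower in shKAP1. They are 26.3% of the 12905 genes that received an adjusted p, a number recovered from the adjusted and raw p-values. The median listed gene differed by 1.22-fold, with quartiles of 1.15 and 1.33. At least 2-fold changes were seen for 82 genes, 45 higher and 37 lower. The 95% interval lay wholly beyond 1.2-fold for 631 genes. Genes not listed either missed the threshold or received no adjusted p, and the table does not tell these apart.

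**Figure D1:**
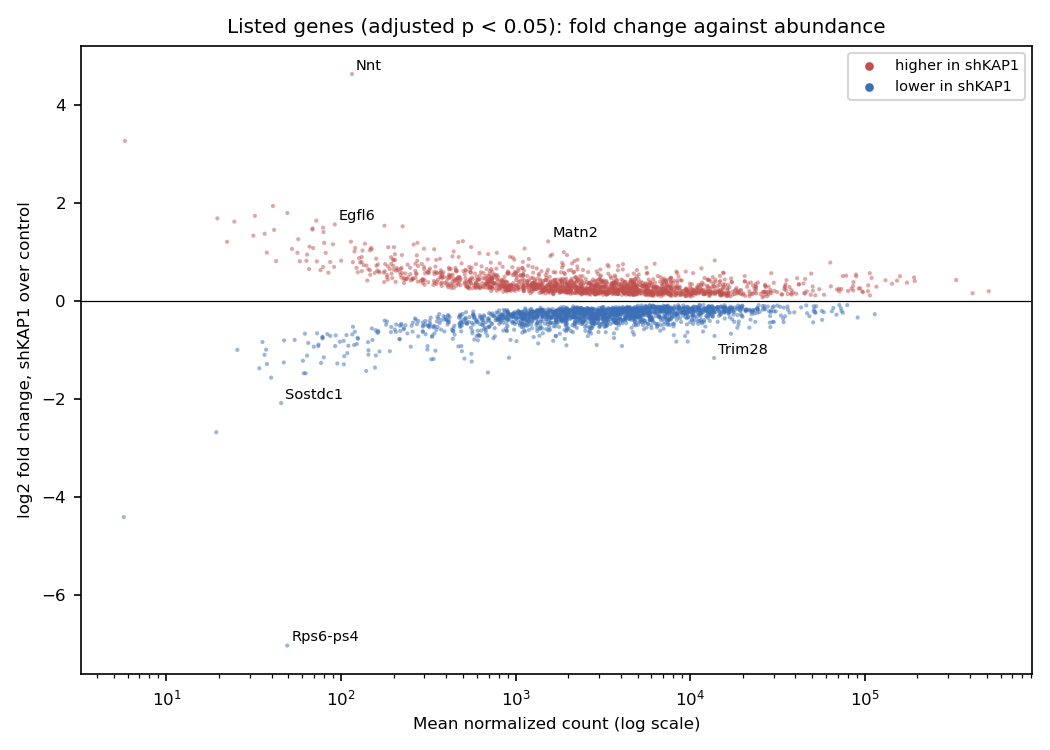
Each point is 1 of the 3389 genes listed at an adjusted p under 0.05, by mean normalized count on a log scale (x axis) and log2 fold change of shKAP1 over control (y axis), red for higher and blue for lower. Most genes lie within 2-fold of no change, Trim28 stands out among abundant genes at -1.17, and Nnt and Rps6-ps4 lie far from the rest.

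Among genes higher by at least 2-fold, the 12 with the smallest adjusted p were Myl9, Cryab, Matn2, Lgals3, Clcf1, Egfl6, Unc5d, Ckmt1, Gna14, Osbp2, Prrt1 and Hist2h3c2. In the authors' deposited table, Myl9, a myosin regulatory light chain, had a log2 fold change of 1.06 (SE 0.12, adjusted p = 1.17e-17, DESeq2), and Cryab, a small heat shock protein, one of 1.07 (SE 0.12). Matn2, an extracellular matrix adaptor, rose by 1.21 (SE 0.15) on the log2 scale of the authors' deposited table, and Lgals3, the lectin galectin-3, by 1.52 (SE 0.19). Clcf1, a cytokine of the IL-6 family, had a log2 fold change of 1.53 (SE 0.25) in the authors' deposited table, and Egfl6, a secreted EGF-domain protein, one of 1.56 (SE 0.26). Unc5d, a netrin receptor family member, stood at 1.15 (SE 0.16) in the authors' deposited table and the mitochondrial creatine kinase Ckmt1 at 1.19 (SE 0.17). The remaining ones were Gna14, a G protein subunit, Osbp2 at 1.22, Prrt1 at 1.00 and Hist2h3c2 at 1.09 in the authors' deposited table. Hist2h3c2 has near-identical histone paralogs, so its reads may be split between copies and its value is uncertain.

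Among genes lower by at least 2-fold, Trim28 was followed by Hs6st2, a heparan sulfate sulfotransferase, at -1.16 (SE 0.11, adjusted p = 8.55e-22, DESeq2) in the authors' deposited table. Bcas1, a marker of oligodendrocytes that are starting to myelinate, fell by 1.03 (SE 0.11) on the log2 scale of the authors' deposited table, and Gper1, a G protein-coupled estrogen receptor, fell by 1.18 (SE 0.15). The authors' deposited table gives Sostdc1, a secreted BMP and Wnt antagonist, at -2.09 (SE 0.38), with a mean normalized count of only 45.4. Lmo7 at -1.02, Igsf21 at -1.19, St6galnac3 at -1.08 and Nt5e at -1.03 were also lower in the authors' deposited table. Pla2g3 at -1.07, Hpgds at -1.10 and Casq2 at -1.13 complete the 12 lower genes in the authors' deposited table.

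Genes of the cell cycle moved together. All 34 genes of the mitosis list were listed and lower, with a median log2 fold change of -0.43 and a range of -0.56 to -0.18. Of the 34 genes of the DNA replication list, 27 were lower, none was higher and 7 were not listed, with a median of -0.30. In the authors' deposited table, Ect2, which drives cytokinesis, stood at -0.55 (SE 0.05, adjusted p = 6.73e-26, DESeq2), the proliferation marker Mki67 at -0.55 (SE 0.05) and the topoisomerase Top2a at -0.45 (SE 0.04). Cenpf, a kinetochore protein, was at -0.48 (SE 0.06), the replication protein Rpa2 at -0.46 (SE 0.06), the helicase subunit Mcm6 at -0.40 (SE 0.05), Cdc45 at -0.40 and Rrm1 at -0.31 in the authors' deposited table. Of all listed genes 47.8% were higher, and both lists held fewer higher members than the other listed genes (Fisher's exact test, two-sided, adjusted p = 3.56e-09 for mitosis and 1.87e-07 for DNA replication, over 16 lists). Only counts of listed members were planned, and this test of direction was chosen after the data were seen, for these and the other lists.

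Genes of the list of p53 targets and apoptosis, shortened below to p53 targets, were mostly higher. Of its 29 genes, 15 were higher, 2 lower and 12 not listed (Fisher's exact test, adjusted p = 0.00473). The median log2 fold change was 0.31. Sesn2, a stress-induced sestrin, stood at 0.51 (SE 0.05, adjusted p = 1.60e-22, DESeq2) in the authors' deposited table, Zmat3, an RNA-binding p53 target, at 0.35 (SE 0.06), the death receptor gene Fas at 0.67 (SE 0.13) and Bbc3, which encodes the pro-apoptotic protein PUMA, at 0.31 (SE 0.06). The cell cycle inhibitor gene Cdkn1a was at 0.33 (SE 0.07) and Mdm2 at 0.29 (SE 0.08) in the authors' deposited table, whereas Trp53inp1 at -0.23 and Bcl2l11 at -0.47 were the 2 lower members.

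Of 40 neural stem cell genes, 11 were higher, 2 lower and 27 not listed, with a median log2 fold change of 0.29 (Fisher's exact test, adjusted p = 0.0320). The glial and progenitor genes Vim, an intermediate filament, at 0.40 (SE 0.04), Fabp7, a fatty acid binding protein of radial glia, at 0.48 (SE 0.05) and the glutamate transporter gene Slc1a3 at 0.47 (SE 0.06) were higher in the authors' deposited table. Id1, a target of BMP signalling, was at 0.77 (SE 0.10), Lrig1 at 0.29 (SE 0.04) and Nes, the progenitor marker nestin, at 0.19 (SE 0.08, adjusted p = 0.0482, DESeq2) in the authors' deposited table, and the lower members were Mki67 and Nfia. Sox2, Pax6 and Gfap, markers of stem cells and their progeny, were not listed. The call did not pass on fewer members, with a similar split, when members shared with other lists were left out (7 higher, 1 lower, adjusted p = 0.0692), at a Bonferroni limit (5 higher, 1 lower, adjusted p = 0.142) and with intervals beyond 1.2-fold (4 higher, 1 lower, adjusted p = 0.289).

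Genes of neuroblasts and young neurons, at 3 higher and 9 lower of 48, did not pass the test of direction (Fisher's exact test, adjusted p = 0.300), which for lists of this size misses many shifts. Dcx, a microtubule protein of migrating neuroblasts, was lower at -0.62 (SE 0.18, adjusted p = 0.00285, DESeq2) in the authors' deposited table, as were Etv1 at -0.38, Ncam1 at -0.26 and Cd24a at -0.33, whereas the RNA-binding protein gene Celf4 was higher at 0.95 (SE 0.19). Dlx2, a transcription factor of interneuron precursors, was not listed. The oligodendrocyte lineage list gave 5 higher and 2 lower of 26 (Fisher's exact test, adjusted p = 0.360). Olig2 was at 0.20 (SE 0.08, adjusted p = 0.0415, DESeq2), Ptprz1 at 0.37, Tcf7l2 at 0.42 and Ugt8a at -0.62 in the authors' deposited table. The highest member of this list was Mobp at 1.03 (SE 0.24) and the lowest Bcas1 at -1.03 in the authors' deposited table. The astrocyte list gave 4 higher and 1 lower of 24 (adjusted p = 0.305), and Cst3 at 0.51, Clu at 0.50 and Aldh1l1 at 0.29 were higher in the authors' deposited table.

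Markers of other cell types that such cultures could hold were seldom listed. None of 20 microglia and macrophage genes was listed. Of 16 endothelial genes, Pltp was higher at 0.61 and Egfl7 lower at -0.70 in the authors' deposited table. Of 20 mural cell and fibroblast genes, 3 were higher, namely the smooth muscle genes Acta2 at 1.03 (SE 0.24) and Tagln at 0.87 (SE 0.22), and Igfbp2 at 0.35 (SE 0.09), in the authors' deposited table. Mean normalized counts were 143289 for Igfbp2 and 132.8 for Acta2, against a median of 2884.6 over listed genes. Igfbp2 was thus far more abundant than Acta2, and whether the 3 genes reflect a change in these cell types was not tested. Of 25 ependymal and ciliary genes, Foxj1 at 0.59 and S100a6 at 0.80 were higher and Myb at -0.73 lower in the authors' deposited table. These 4 lists had fewer than 5 listed members each and were not tested.

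Listed genes of the KAP1 complex and its partners were mostly lower. Their list holds partners of KAP1 and does not address whether genes repressed by KAP1 rose. Of 25 genes of the KAP1 repressor complex and its partners, 12 were lower and 1 higher (Fisher's exact test, adjusted p = 0.0149), and without Trim28 the split was 11 lower and 1 higher (unadjusted p = 0.00681). The lower members included the DNA methyltransferase gene Dnmt1 at -0.31 (SE 0.05), Uhrf1 at -0.28 (SE 0.06), Chd4 at -0.22 (SE 0.04) and the histone methyltransferase gene Setdb1 at -0.16 (SE 0.05) in the authors' deposited table. Dnmt1 and Uhrf1 also act at replicating DNA, and Uhrf1 stands on the DNA replication list as well. The higher member was Zfp57, a KRAB zinc finger gene needed for imprint maintenance, at 0.67 (SE 0.25, adjusted p = 0.0336, DESeq2) in the authors' deposited table.

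Imprinted genes split into 4 higher and 6 lower of 46 (adjusted p = 0.806). Peg10 at -0.70 (SE 0.13) and the cell cycle inhibitor gene Cdkn1c at -1.36 (SE 0.38) were lower in the authors' deposited table, as were Ppp1r9a at -0.50 and Igf2r at -0.43, and Blcap at 0.38 and Gnas at 0.24 were higher. The family of genes named Zfp split into 19 higher and 25 lower of 400 (adjusted p = 0.675), with Zfp385a at 0.39, Zfp768 at 0.32, Zfp651 at 0.37 and Zfp367 at -0.49 in the authors' deposited table. None of 34 germline and 2-cell-stage genes was listed. In the neighbourhood of Pax6 and the noncoding RNA gene Paupar, 1 of 12 genes was listed, Mpped2 at -0.42 (SE 0.08) in the authors' deposited table, and Paupar was not listed in a table where 3378 of 3389 genes are protein-coding.

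Interferon response genes were 10 higher and 3 lower of 49, which did not pass the correction (Fisher's exact test, adjusted p = 0.112). Irf9 at 0.35 (SE 0.09) and Trim25 at 0.34 (SE 0.07) were higher in the authors' deposited table, whereas the chemokine gene Cxcl10 was lower at -0.92 (SE 0.13, adjusted p = 2.86e-11, DESeq2). Extracellular matrix and adhesion genes were 11 higher and 3 lower of 30 (adjusted p = 0.0780), with Sparc at 0.46 (SE 0.04), Ncan at 0.50 (SE 0.05) and Nid1 at 0.46 (SE 0.09) higher and the integrin gene Itgb1 at -0.21 (SE 0.04) lower in the authors' deposited table. The stress list gave 7 higher and 3 lower of 28 (adjusted p = 0.305). Hmox1 at 0.75 (SE 0.10), Srxn1 at 0.73 (SE 0.12) and the stress factor gene Atf3 at 0.83 (SE 0.18) were higher in the authors' deposited table. The thioredoxin reductase gene Txnrd1 at -0.15 (SE 0.04) and the chaperone gene Hspa5 at -0.18 (SE 0.04) were lower in the authors' deposited table.

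None of the signalling and metabolic lists that could be tested passed the test of direction. The Notch list gave 2 higher and 3 lower of 23 (adjusted p = 1), with the fringe genes Mfng at -1.19 (SE 0.31), Lfng at 0.29 and Rfng at 0.18 and the effector gene Rbpj at -0.32 in the authors' deposited table. The BMP and Wnt list gave 3 higher and 2 lower of 29 (adjusted p = 0.771), with Id2 at 0.52 and Wnt7a at 0.33 higher and the Wnt feedback gene Axin2 at -0.44 (SE 0.06) lower in the authors' deposited table. Cholesterol synthesis genes were 2 higher and 7 lower of 24 (adjusted p = 0.305), including Hmgcs1 at -0.24, Stard4 at -0.31 and Tm7sf2 at 0.26 in the authors' deposited table. The Shh list held 3 lower genes of 12, Gas1 at -0.30, Cdon at -0.38 and Gli3 at -0.30, and the hypoxia and glycolysis list 3 lower genes of 24, Pkm at -0.27, Ldha at -0.24 and Tpi1 at -0.18, in the authors' deposited table. Neither reached the 5 listed members required for a test.

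**Figure D2:**
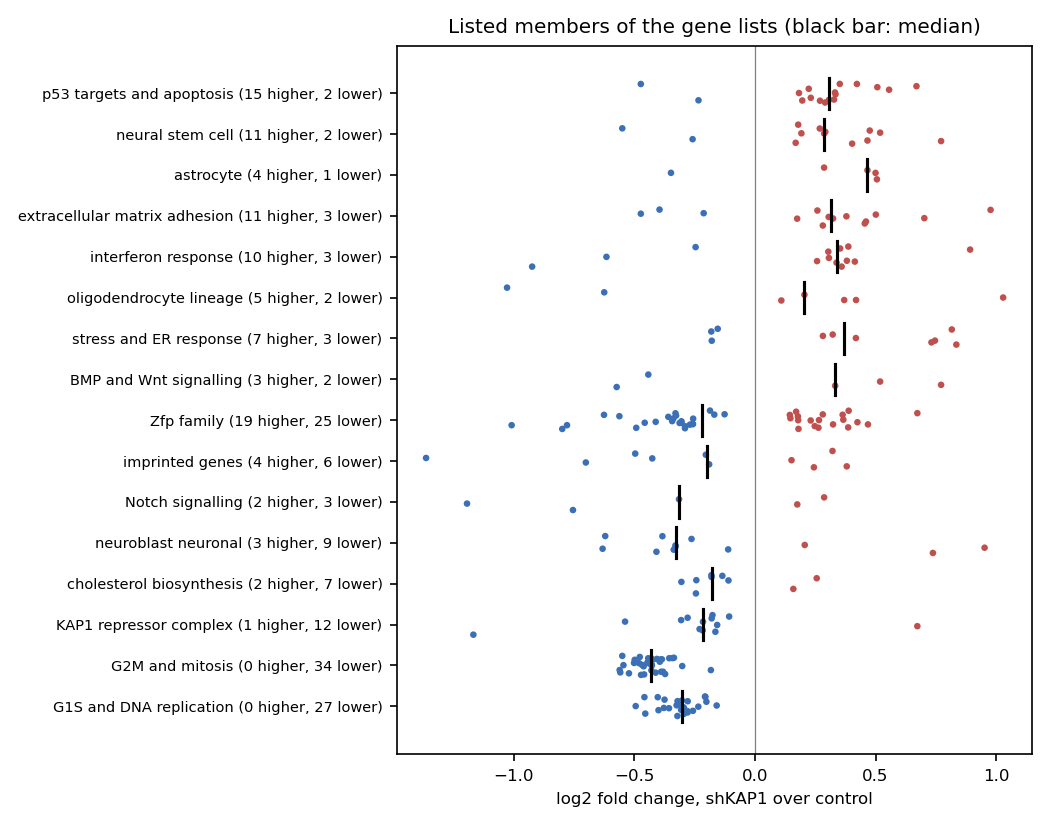
Each row is a gene list with at least 5 listed members and each point a listed member, placed by its log2 fold change of shKAP1 over control on the x axis, red for higher, blue for lower and a black bar for the median. The mitosis list (0 higher, 34 lower) and the DNA replication list (0 higher, 27 lower) lie wholly below 0, and the p53 list (15 higher, 2 lower) mostly above.

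Direction was related to base composition. Among listed genes in the lowest quintile of transcript GC content (31.9% to 44.7%), 25.1% were higher in shKAP1, against 70.1% in the highest quintile (56.2% to 69.1%), and across genes Spearman's rho between GC content and log2 fold change was 0.28. Genes are not independent replicates, so no p is given. Against draws of listed genes, matched on GC content and also chosen after the data were seen, the same 5 lists passed, with adjusted p = 0.0016 for both cell cycle lists, 0.00640 for p53 targets, 0.0256 for the KAP1 list and 0.0275 for neural stem cell genes. All 16 listed transcripts of the mitochondrial genome were higher, at log2 fold changes of 0.27 to 0.93, with 21 of 37 not listed. The 37 include transfer and ribosomal RNA genes, which poly(A)-selected libraries may measure poorly, so those not listed are not shown to be unchanged.

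**Figure D3:**
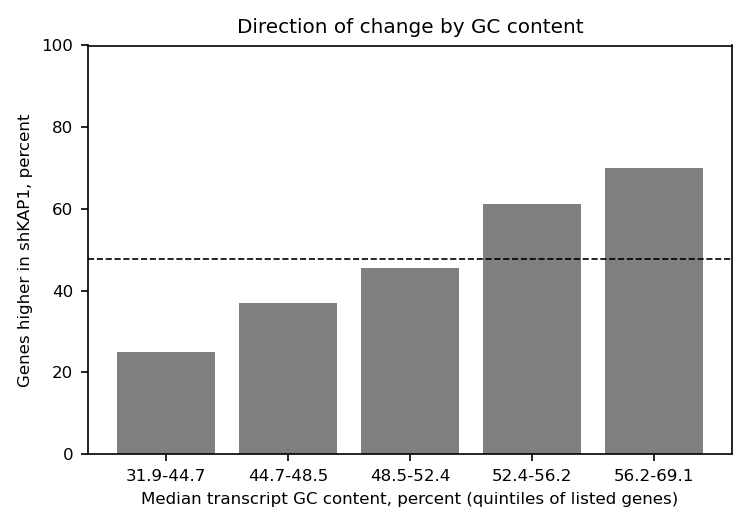
Bars give the percentage of listed genes that were higher in shKAP1 (y axis) in each quintile of median transcript GC content in percent (x axis), and the dashed line marks the 47.8% of all listed genes that were higher. The share climbs from 25.1% in the lowest quintile to 70.1% in the highest.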

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

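The values came from 1 deposited table of genes past a threshold, so most of the variations intended could not be made: other tools, normalizations, filters and pseudocounts, set tests with camera or fry, leaving out single replicates and other splits of the samples all need values per sample. No paired analysis was possible because the table has no column per sample, although library numbers 1, 2 and 4 occur in both groups. The Bonferroni limit, the minimum count, the 1.2-fold bound, the GC-matched draws and the restriction to members on no other list were chosen after seeing the data. The 3389 listed genes became 82 with a 2-fold minimum, 930 at the Bonferroni limit and 631 with an interval beyond 1.2-fold, by construction fewer. At an adjusted p under 0.01 they were 2283, and at a mean normalized count of at least 100 they were 3318. The share higher, 47.8% in all, was 54.9% with the 2-fold minimum and 42.4% at the Bonferroni limit. Trim28 passed all 5 of these settings. Of the 101 named genes that were listed, 26 passed the 2-fold minimum and 62 the 1.2-fold bound. Of the 5 lists past the test of direction, 3 still passed at the Bonferroni limit (mitosis, DNA replication and p53 targets), where the KAP1 list had under 5 members left, and 1 with the 1.2-fold bound (mitosis), where DNA replication, p53 targets and the KAP1 list had under 5 members left. With the 2-fold minimum no list could be tested. None of the 5 lists past the test reversed its direction under any setting run. The settings reuse the same listed genes and fold changes, so a reversal of these lists was hardly possible. Lists that did not pass could tip over, such as the Zfp family, at 19 higher and 25 lower in all and 6 higher and 3 lower at the Bonferroni limit.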

Other observations

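All tests in this part were chosen after the results were seen. A scan of 34 gene families by symbol prefix gave 28 with at least 5 listed members, and the p-values below were adjusted over these 28. The families named were picked for their direction or as a contrast, and some were narrowed after their members were seen, so the p-values rank them but do not stand as independent evidence. All 28 listed genes of the nuclear-encoded respiratory chain family, of 97 annotated, were higher (Fisher's exact test against other listed genes, adjusted p = 2.67e-08). Its prefixes also took in ATP synthase genes, such as Atp5d at 0.22, and assembly factor genes, such as Ndufaf5 at 0.22, in the authors' deposited table. The amounts were small, around a median log2 fold change of 0.16, with the succinate dehydrogenase subunit gene Sdha at 0.14 in the authors' deposited table. All 16 listed transcripts of the mitochondrial genome were higher too, with 21 of 37 not listed (Fisher's exact test, adjusted p = 6.74e-05). Their median was 0.50, including mt-Co1 at 0.42 and mt-Nd1 at 0.54 in the authors' deposited table. All lie on 1 genome, so the count and its p rest largely on 1 locus. The 37 include transfer and ribosomal RNA genes, which poly(A)-selected libraries may measure poorly, so those not listed are not shown to be unchanged. The median GC content of the 16 listed transcripts was 36.5%, and 25.1% of listed genes in the lowest GC quintile were higher. GC-matched draws gave 3.49 higher of 16 (adjusted p = 0.0028). The family was picked for its direction, so these draws cannot decide whether a GC-dependent bias contributed. RNA quality per library was not examined. Mitochondrial ribosomal protein genes were 12 higher and 2 lower (adjusted p = 0.0193) but did not pass the GC-matched draws (adjusted p = 0.105), and cytosolic ribosomal protein genes were 4 higher and 4 lower (adjusted p = 1). Genes of lysosomal enzymes and the proton pump were 9 higher and 1 lower (adjusted p = 0.0276).

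All 25 listed hnRNP, SR protein and small nuclear ribonucleoprotein genes, of 43 annotated with 18 not listed, were lower (Fisher's exact test, adjusted p = 1.24e-06), among them the spliceosome core gene Snrpb at -0.47 and Hnrnpa1 at -0.39 in the authors' deposited table. All 12 listed nucleoporin genes and all 12 listed centromere protein genes were lower as well (adjusted p = 0.00302 for each), with 9 of 21 not listed in each family. The centromere protein genes overlap the cell cycle genes reported above, 3 of them (Cenpa, Cenpe and Cenpf) standing on the fixed lists, and are not a separate result. Clustered protocadherin genes, which encode cell surface adhesion proteins, were 15 higher and 2 lower of 56 (adjusted p = 0.00414), with Pcdhgc5 at 0.70 and Pcdhb17 at 0.46 in the authors' deposited table. Of the higher ones 12 lie in the gamma cluster and 3 in the beta cluster, and both lower ones in the alpha cluster. Members of the gamma cluster share constant exons, as do those of the alpha cluster, so single values are uncertain and the count and its p rest largely on 1 locus. Actin, myosin light chain and calponin family genes were 12 higher and 1 lower of 30 (adjusted p = 0.00492), led by the smooth muscle genes Myl9 at 1.06, Acta2 at 1.03 and Tagln at 0.87 in the authors' deposited table, of which Acta2 and Tagln also stand on the mural cell and fibroblast list. Cnn2 at 0.58 and Flna at 0.38 were higher too in the authors' deposited table, and a change in the cells present was not tested. The 4 listed genes of fatty acid synthesis and elongation were all lower, too few to test, with the elongase gene Elovl6 at -0.83 (SE 0.05, adjusted p = 5.39e-54, DESeq2) in the authors' deposited table. Of the 28 families, 9 passed Fisher's exact test and 8 the GC-matched draws. The other families, among them solute carrier (42 higher, 26 lower, adjusted p = 0.0677), kinesin (4 higher, 15 lower, adjusted p = 0.0587), histone, proteasome, tubulin and collagen genes, did not pass.

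The joint fall of DNA replication and mitosis genes (61 of 61 listed genes lower) was set against the GC trend, since these genes had a median GC content of 47.5% against 50.4% in other listed genes. GC-matched draws predicted 24.4 higher genes and 0 were seen (permutation p = 0.0001, the smallest the draws can give). The GC trend among listed genes thus does not on its own give this shared direction. The draws were made after the direction was known, count directions and not sizes, and treat co-regulated genes as independent. They do not show how much of the fall a GC-dependent difference between libraries made. A lower share of cycling cells may account for the fall and stays open. The mitosis list lay -0.13 from the DNA replication list in median log2 fold change (permutation p = 1.00e-05, the smallest these draws can give). These draws shuffled list labels among genes, treating co-regulated genes as independent, so their p does not measure the spread between samples. An equal fall of both lists was written down, after results were partly seen, as the outcome of fewer cycling cells. It was not met. The gap neither excludes nor requires a lower share of cycling cells, because replication genes are less confined to 1 phase. Lower transcription per cell after Trim28 loss was not tested, and a table without cell counts cannot separate it from a change in the cells present.

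The largest rise in the table was that of Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase gene on chromosome 13 (GRCm38, 119335528 to 119408952), at a log2 fold change of 4.62 with an SE of 1.72 (adjusted p = 0.0303, DESeq2) in the authors' deposited table. C57BL/6J mice carry a deletion in Nnt that other strains lack, so a candidate explanation is that the cultures came from animals of differing Nnt genotype, unevenly spread over the groups. The dispersion implied by the SE, assuming 3 control and 4 shKAP1 libraries of equal depth, which the table does not state, was 2.35, against a median of 0.0203 and a 95th percentile of 0.0941 in 374 other listed genes with a mean normalized count of 20 to 500. Genes with a wide error seldom pass the authors' test, so these peers are narrower than unselected genes and the comparison overstates how unusual Nnt was. Under the assumed library numbers the value itself means that libraries of the same group differed widely. A gene carried by a few libraries for any other reason would give it too, and the pseudogene Rps6-ps4, at -7.03 (SE 2.08) in the authors' deposited table, reached 3.07, so genotype cannot be told apart from other library differences without values per sample.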
